A study of Homo sapiens with 6 samples.

How the data were processed

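RNA was measured in 6 libraries of the human beta cell line EndoC-βH1, 3 with the empty vector and 3 with the guide sgZHX3-3, per the labels. Total RNA was extracted with a NucleoSpin RNA kit and libraries were made with a stranded NEBNext Ultra Directional kit, per the labels' protocols. Reads were aligned with STAR to hg38 and counted with featureCounts, per the submitters' processing notes. The versions, the gene annotation, the strand setting and the treatment of reads with several matches are not given in the sources used here. The deposited values are raw counts per gene symbol, 1 column per library, with no normalisation, per the file headers and as whole numbers in the values. Columns were joined to samples by group name and replicate letter, per the file headers and the labels. No value column was left without a sample.

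All other values were computed from these counts. Gene symbols were matched to GENCODE release 29 (GRCh38), in which 24603 of 26485 symbols (92.9%) were found, for coordinates, gene span and gene type. Members of the gene lists were matched through older symbols where needed, which placed 24 members. Genes were kept by filterByExpr of edgeR with a minimum count of 10 and a minimum total count of 15, which left 16199 genes. Library sizes were scaled by TMM, with factors from 0.984 to 1.02. The libraries held 45101454 to 61051884 counts each, and the common biological coefficient of variation was 6.91%. The comparison of the libraries labelled sgZHX3-3 with those labelled Empty used edgeR's robust quasi-likelihood test with group as the only term and Benjamini-Hochberg adjustment, called at 0.05. Standard errors were derived from the fold change and the F statistic. CPM values use TMM library sizes. Tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Seurat 5.3.0, Python 3.11.15 and matplotlib 3.10.9.

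The tests, the thresholds, 39 gene lists and the rule for naming genes were chosen before the data were examined. Lists with at least 5 tested members (38) were tested with camera of limma at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists; counts of members adjusted over the list alone are given beside them. By the rule the text may name ZHX3, the 15 genes with the largest and the 15 with the smallest log2 fold change among called genes with a mean of at least 1 CPM, no overlap of the groups and an ordinary gene symbol, up to 5 called members with the smallest adjusted p in each list, a fixed set of beta cell genes, and the neighbours of ZHX3. HSPA1A and DNAJB1, and the called list members ERN1, DUSP6, FADS2, SPINK1, SNAI1, TGFBR2, NFKBIZ, NPC1, CCNB1 and AURKA, which lie outside the rule, were chosen after their values were seen, as were the named members of the added lists and the named long genes.

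The alternatives fixed at the start were RLE size factors, library totals only, no expression filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, each library left out in turn, a log2 fold change limit of 1, an adjusted p below 0.01, an estimated correlation and the rotation test fry. Added after the data were seen were an offset for gene span, an offset for transcript length and GC content, Empty 2 and 3 left out together, and S-phase, G2/M (both from Seurat) and heat shock gene lists.

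The procedure was tested on simulated counts for this comparison with 200 changed genes among 16073 tested. It recovered 47.8% of genes changed 1.25-fold, 74.6% of those changed 1.5-fold and 93.9% of those changed 2-fold, and 12 of 156 calls were false. Of 30 random lists of 25 genes 0 were called by camera, and a list of changed genes was called. The simulated genes varied independently of each other, while the estimated correlation in the real lists reached 0.51. The simulation therefore could not show false list calls that come from correlation between genes. Mitochondrially encoded genes were left out since the table holds none. Reads were not used here, so the edit made by the guide, its position and splicing of ZHX3 were not analysed here. Values of some genes of the lists are not reported here.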

Results

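Bulk RNA sequencing was done on 6 cultures of EndoC-βH1, a human pancreatic beta cell line that makes and secretes insulin. By the labels, all cultures carried lentiCRISPRv2, a lentiviral vector that delivers the Cas9 nuclease together with an antibiotic resistance gene. In 3 libraries, named Empty, the vector held no guide RNA. In the other 3, by their labels, it held a guide, sgZHX3-3, against the first coding exon of ZHX3, and the cells were kept as antibiotic-selected stable lines. The titles number biological replicates 1 to 3 in each group, and the genotype label of the guide group is ZHX3 KO. The titles do not say whether the replicates are separately made lines or repeat cultures of the same line. The SDs, standard errors and p-values may therefore measure spread between cultures only. The deposited table held whole-number counts for 26485 gene symbols, of which 5246 had no count in any library. Total counts were 46624747, 58167871 and 48299163 in Empty 1, 2 and 3, and 45101454, 50688946 and 61051884 in sgZHX3-3 libraries 1, 2 and 3. The chromogranin gene CHGA had the highest count in each library, and the 10 most abundant genes took between 5.52% and 6.59% of the counts. Empty 1 stood apart from Empty 2 and 3 on the first principal component, which held 43.6% of the variance: the Empty libraries lay at −6.34, −19.9 and −23.8, and the sgZHX3-3 libraries at 12.3, 15.6 and 22.1. The second component held 20.2% and set Empty 1 (20.9) and sgZHX3-3 library 3 (10.8) on the same side, across the groups. On it Empty 2 and 3 lay at −5.02 and −4.14, and sgZHX3-3 libraries 1 and 2 at −14.5 and −8.06. By the chi-square per gene between pairs of libraries, which grows with depth, Empty 1 lay at 22.2 from Empty 2 and 21.3 from Empty 3. It lay at 18.2, 20.6 and 27.4 from sgZHX3-3 libraries 1, 2 and 3, the lowest value being with the library of fewest counts. By Spearman correlation Empty 1 was instead nearest to Empty 2 (0.9868) and least near to sgZHX3-3 library 1 (0.9863). Which library lay nearest to Empty 1 thus depends on the measure. The guide group was not uniform either. By chi-square its library 3, the deepest, lay at 20.3 from library 1 and 12.3 from library 2. Libraries 1 and 2 of that group lay at 4.43 from each other. The question was how deletion of ZHX3, a zinc-finger and homeobox protein that represses transcription, changes the RNA of beta cells. By the labels all libraries of the guide group carry the same guide. An effect of losing ZHX3 therefore cannot be told apart from other effects of that guide, or from other differences between the groups.

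ZHX3 RNA was higher, not lower, in the libraries labelled as carrying the guide. It was at 105 ± 4.19 CPM (SD, n = 3) in Empty and 177 ± 8.62 CPM (SD, n = 3) in sgZHX3-3, a log2 fold change of 0.75 with a standard error of 0.0566 (edgeR adjusted p = 1.62e-05). The counts were 4938, 6484 and 4969 in Empty 1 to 3 and 7465, 8976 and 11046 in the sgZHX3-3 libraries, so the groups did not overlap. This goes against a reading of the label as a loss of the RNA, and the groups are therefore called the libraries labelled Empty and the libraries labelled sgZHX3-3, and each direction given here is drawn from those labels. Small insertions and deletions made by Cas9 need not lower the level of an RNA, so the RNA level checks the labels only in part, and the protein was not analysed here. ZHX3 (ENSG00000174306.21) lies on the minus strand of chromosome 20 from 41178448 to 41317672 in GRCh38. In its transcript ENST00000544979.6 the first coding exon is exon 4, from 41202283 to 41204916, which holds 90.6% of the coding bases. The 3′ part of ZHX3 overlaps PLCG1, which lies on the plus strand from 41136960 to 41196801, and the strand setting of the counting is not given in the sources used here, so both counts are uncertain where the genes overlap.

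The genes around ZHX3 moved far less than ZHX3 itself. Of the 8 genes in the fixed list of the 20q12 region, ZHX3 included, 3 were higher and 0 lower. Beside ZHX3 the higher ones included the receptor phosphatase gene PTPRT (log2 fold change 0.31, edgeR adjusted p = 0.00223). PTPRT is a very long gene, and its value was −0.03 once a trend with gene span had been removed. The 5 genes that did not pass were TOP1 (0.03), PLCG1 (0.17, adjusted p = 0.0581), LPIN3 (0.11), EMILIN3 (0.20) and CHD6 (0.14). PLCG1 passed without sgZHX3-3 library 1 (adjusted p = 0.0348) and with DESeq2 (0.0361), and LPIN3 and EMILIN3 are uncertain as close neighbours. The list as a set, with ZHX3 in it, had a median of 0.19 (camera adjusted p = 1.07e-05; adjusted p = 0.219 with an estimated correlation), and 4 members were higher and 0 lower adjusted over the list alone. Of the list of the ZHX family and the NF-Y subunits, with which ZHX proteins bind, ZHX3 was higher and NFYC lower among 7 tested genes. NFYC was at −0.26 (edgeR adjusted p = 0.0188) and lost its call without Empty 2 (0.0784), Empty 3 (0.103) or sgZHX3-3 library 2 (0.108). ZHX1 (−0.06, adjusted p = 0.507) and ZHX2 (0.43, adjusted p = 0.0669) did not pass, and the list was not called (camera adjusted p = 0.305), with a median of −0.06, a mean of 0.10 and a test direction upward.

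**Figure D1:**
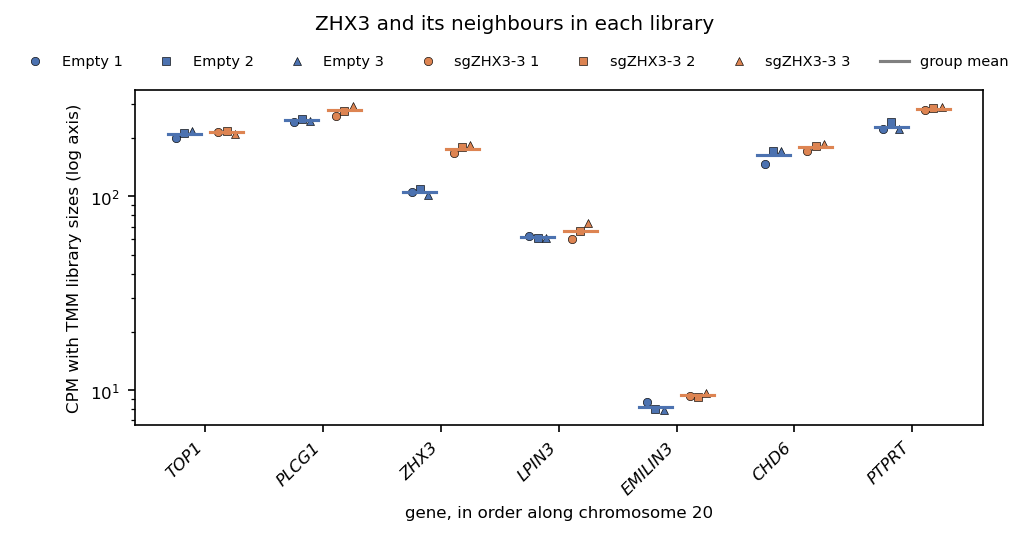
CPM with TMM library sizes on a log axis for ZHX3 and 6 neighbours in their order on chromosome 20; each symbol is 1 library (blue, Empty; orange, sgZHX3-3) and bars are group means. ZHX3 had group means of 105 and 177 CPM with no overlap, against 211 and 215 CPM for TOP1.

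Of 16199 genes tested, 1151 were higher and 807 lower in the libraries labelled sgZHX3-3 (edgeR, adjusted p below 0.05), and most changes were small. The median log2 fold change was 0.35 among the higher genes and −0.31 among the lower ones, and 60 and 46 genes respectively changed by at least the log2 limit of 1. The groups did not overlap for 32.0% of all tested genes, where chance gives 10% on average. Genes vary together, so the share under chance can lie far from that average. Among the called genes the share was 99.0%, which follows largely from how they were chosen. Protein-coding genes made up 1088 of the higher and 777 of the lower genes. Of the called genes 58.8% were higher; this share was 41.5% when libraries were scaled by their totals alone, with 904 higher and 1272 lower. It was 48.4% once a trend with gene span had been removed (890 higher and 949 lower) and 50.8% once trends with transcript length and GC content had been removed (1136 and 1099), so which direction holds more genes depends on the scaling. The counts depended on single libraries: they were 1792 higher and 1499 lower without Empty 1, 559 and 231 without Empty 2, 474 and 184 without Empty 3, 492 and 211 without sgZHX3-3 library 2, and 834 and 415 without sgZHX3-3 library 3. With Empty 2 and 3, whose stress genes stood apart, both left out, 209 genes were higher and 40 lower, 160 and 37 of them also called with all libraries; the lone Empty library is then assumed to vary like the others, and a call lost in that setting does not by itself show that a change rested on Empty 2 and 3.

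The 15 strongest rises by the naming rule included genes for neurotransmitter receptors and metalloproteases, classes for which no list was tested. GRM4, a metabotropic glutamate receptor, went from 8.05 ± 0.449 CPM (SD, n = 3) to 19.5 ± 0.611 CPM (SD, n = 3), a log2 fold change of 1.27 with a standard error of 0.0799 (edgeR adjusted p = 1.13e-05). The nicotinic receptor subunits CHRNA3 and CHRNA4 rose by 1.62 (adjusted p = 8.13e-05) and 1.37 (adjusted p = 5.32e-05), and the NMDA receptor subunit GRIN2A rose by 1.14. The sorting receptor SORCS2 rose by 1.65 and the adhesion protein SDK2 by 1.24 (adjusted p = 2.17e-05). The largest rise by the naming rule was that of PTCHD4, a patched-domain membrane protein, at 1.75 with a standard error of 0.170 (adjusted p = 7.08e-05), from 1.08 to 3.64 CPM. The metalloproteases ADAMTS7, MMP2 and ADAM12 rose by 1.42, 1.31 and 1.15, and the matrix protein SPON1 by 1.24, from 16.2 ± 2.69 CPM (SD, n = 3) to 38.2 ± 6.65 CPM (SD, n = 3). The remaining genes of the 15 were VSTM2B (1.43), the transcription factors SOX8 (1.41) and TBX1 (1.18), and the amino acid transporter SLC6A19 (1.19). Of these 15, SORCS2, GRIN2A, ADAM12, SDK2 and SPON1 span over 300 kb, and 31.9% of all tested genes of that span were higher. All 15 kept their call with any 1 library left out. With Empty 2 and 3 both left out, VSTM2B (1.03, adjusted p = 0.147), TBX1 (1.03, 0.0590) and ADAM12 (0.95, 0.197) lost it.

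The 15 strongest falls included several genes of the NRF2-driven oxidative stress response beside transporters and structural genes. TXNIP, which binds thioredoxin and is induced by glucose, went from 1.90 ± 0.301 CPM (SD, n = 3) to 0.299 ± 0.0872 CPM (SD, n = 3), a log2 fold change of −2.69 (edgeR adjusted p = 7.08e-05). SYNPO, an actin-associated protein, went from 12.3 ± 1.401 CPM (SD, n = 3) to 4.43 ± 0.382 CPM (SD, n = 3), at −1.46 with a standard error of 0.112 (adjusted p = 1.62e-05). The ion cotransporter SLC12A1 (−2.21), the protease MEP1B (−1.97), the water channel AQP10 (−1.87), the galectin LGALS3 (−1.80) and the secreted trefoil peptide TFF1 (−1.19) also fell. These 7 genes kept their call with any 1 library left out and with Empty 2 and 3 both left out. PIR, another NRF2-linked gene, fell by 1.253 and kept its call with any 1 library left out, but not with Empty 2 and 3 both left out (−0.49, adjusted p = 0.400). The calls of the other 7 changed when single libraries were left out, while their fold changes kept their sign. HSPA6, a heat-inducible chaperone, was at −3.25 (adjusted p = 0.0407), NQO1 at −1.86 (0.0479) and TXNRD1 at −1.16 (0.0453), and each lost its call without any library other than Empty 1, with adjusted p from 0.0669 to 0.122, from 0.112 to 0.159 and from 0.0847 to 0.143. OSGIN1 at −1.49 (0.0490) and SRXN1 at −1.28 (0.0246) lost it without Empty 2 or any of the sgZHX3-3 libraries, with adjusted p from 0.101 to 0.174 and from 0.0647 to 0.102. HMOX1 at −2.56 (0.0130) lost it without Empty 2 (0.0517) or sgZHX3-3 library 2 (0.0670), and FOSB at −1.22 (0.0156) without Empty 2 (0.0542) or sgZHX3-3 library 2 (0.0759). With any 1 library left out NQO1 stayed between −2.14 and −1.64 and SRXN1 between −1.49 and −1.09. With Empty 2 and 3 both left out NQO1 (−1.01, 0.0105), TXNRD1 (−0.59, 0.0165), SRXN1 (−0.72, 0.00558) and OSGIN1 (−0.63, 0.0488) passed with smaller changes, and HSPA6 (−1.70, 0.110043), HMOX1 (−1.52, 0.0706) and FOSB (−0.55, 0.397) did not pass.

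Genes of beta cell identity were higher or did not pass; none of the list was lower. Of 27 tested beta cell transcription factors, 11 were higher and 0 lower, with the same counts of 11 and 0 adjusted over the list alone. NKX6-1 rose by 0.41 with a standard error of 0.0743 (edgeR adjusted p = 0.00390), from 176 ± 20.4 CPM (SD, n = 3) to 234 ± 11.8 CPM (SD, n = 3), and SIX2 by 0.34 (adjusted p = 0.00487); both kept their call with any 1 library left out. PDX1, the main activator of the insulin gene, went from 537 ± 76.8 CPM (SD, n = 3) to 711 ± 42.4 CPM (SD, n = 3), at 0.41 (adjusted p = 0.0115), and lost its call without Empty 2 (0.0528), Empty 3 (0.0581) or sgZHX3-3 library 3 (0.0643). MAFA was at 0.60 (adjusted p = 0.0490) and lost its call without any library other than Empty 1, with adjusted p from 0.0560 to 0.155, and with RLE factors (0.0501). With Empty 2 and 3 both left out, none of these 4 passed: NKX6-1 was at 0.23, SIX2 at 0.34, PDX1 at 0.19 and MAFA at 0.26. NEUROD1 (0.0035, adjusted p = 0.974), PAX6 (0.03, 0.751) and NKX2-2 (0.17, 0.305) did not pass; NKX2-2 passed without Empty 1 (0.00715). The list had a median log2 fold change of 0.10 (camera adjusted p = 6.49e-05, and 0.219 with an estimated correlation). With Empty 2 and 3 both left out its median was 0.13.

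Several genes for glucose sensing and excitability rose and none of that list fell. Of 31 tested genes for glucose sensing and excitability, 13 were higher and 0 lower, and 19 were higher and 0 lower adjusted over the list alone. ABCC8, the sulfonylurea receptor subunit of the ATP-sensitive potassium channel, rose from 546 ± 10.6 CPM (SD, n = 3) to 765 ± 10.2 CPM (SD, n = 3), at 0.49 with a standard error of 0.0475 (edgeR adjusted p = 7.08e-05). The calcium release channels ITPR3 and RYR2 rose by 0.49 (adjusted p = 0.000221) and 0.52 (0.000765), and the calcium channel CACNA1C by 0.37 (0.00121). CACNA1C lost its call with Empty 2 and 3 both left out (0.32, adjusted p = 0.0697) or once a trend with gene span had been removed (0.197). KCNJ11, the pore subunit that pairs with ABCC8, was at 0.26 (0.0353) and lost its call without Empty 2 (0.160), Empty 3 (0.161), sgZHX3-3 library 2 (0.10996) or sgZHX3-3 library 3 (0.124), and with library totals alone (0.0526). The glucose transporter SLC2A2 (0.05, 0.739) did not pass. The list had a median of 0.26 (camera adjusted p = 1.57e-10, and 0.227 with an estimated correlation). With Empty 2 and 3 both left out its median was 0.12.

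Several granule cargo genes rose, while the insulin gene itself did not pass. INS was at 5656 ± 733 CPM (SD, n = 3) in Empty and 6431 ± 674 CPM (SD, n = 3) in sgZHX3-3, a log2 fold change of 0.19 with a standard error of 0.0935 (edgeR adjusted p = 0.219); it passed without Empty 1 (0.0155). INS and IGF2 share the readthrough gene INS-IGF2, so their counts are uncertain. Of 24 tested genes of insulin production and granule cargo, 7 were higher and 0 lower, and 9 and 0 adjusted over the list alone. IAPP, the amyloid peptide released with insulin, went from 631 ± 120 CPM (SD, n = 3) to 962 ± 64.8 CPM (SD, n = 3), at 0.61 (adjusted p = 0.0113), and lost its call without sgZHX3-3 library 3 (0.0686) and with Empty 2 and 3 both left out (0.32, 0.101). The granule membrane protein PTPRN2 rose by 0.55 (0.000490) and IGF2 by 0.46 (0.000492), both with any 1 library left out; PTPRN2 lost its call once a trend with gene span had been removed (0.0576). The prohormone convertase PCSK1 was at 0.23 (0.0176) and the granule zinc transporter SLC30A8 at 0.47 (0.0260). PCSK1 lost its call without Empty 2 (0.0745), Empty 3 (0.103), sgZHX3-3 library 1 (0.0583) or sgZHX3-3 library 2 (0.0862), and SLC30A8 without the same libraries (0.0615, 0.05004, 0.0509 and 0.0945). The list had a median of 0.19 (camera adjusted p = 2.30e-05; adjusted p = 0.398 with an estimated correlation) and was not called with Empty 2 and 3 both left out (0.161). In the means over the list, Empty 1 lay at 0.01, Empty 2 and 3 both at −0.16, and the sgZHX3-3 libraries at 0.07, 0.11 and 0.13 log2 units from the mean of all libraries.

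Some members of the exocytosis and diabetes gene lists rose, while most did not pass. Of 29 tested genes of the exocytosis machinery, 5 were higher and 0 lower (6 and 0 adjusted over the list alone), namely CADPS, CPLX2, RIMS2, the priming factor UNC13A and the syntaxin STX1A, with a list median of 0.13 (camera adjusted p = 0.0389; adjusted p = 0.411 with an estimated correlation). This list lost its call without Empty 2 (0.0598), Empty 3 (0.125) or sgZHX3-3 library 3 (0.0641), with library totals alone (0.0684), with a filter of 1 CPM in 3 libraries (0.0637), and with Empty 2 and 3 both left out (0.546). Of 34 tested genes tied to type 2 or monogenic diabetes, 9 were higher and 2 lower, and 11 and 2 adjusted over the list alone. ABCC8 and the coregulator ZMIZ1 (0.42, edgeR adjusted p = 0.000236) rose and kept their call in each setting that left libraries out. The transcription factor KLF11 (−0.55, 0.000962) and the endoplasmic reticulum stress kinase EIF2AK3 (−0.36, 0.00484) fell, and neither passed with Empty 2 and 3 both left out, when KLF11 was at −0.39 (0.0970) and EIF2AK3 at −0.24 (0.245). The diabetes list had a median of 0.09 (camera adjusted p = 0.0123; adjusted p = 0.219 with an estimated correlation) and was not called with Empty 2 and 3 both left out (0.206).

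Several genes that defend against oxidative stress fell, and their levels differed among the Empty libraries. Of 24 tested genes, 12 were lower and 0 higher, and 13 and 0 adjusted over the list alone. GCLM, which makes the regulatory subunit of the glutathione-synthesis enzyme, went from 160 ± 26.1 CPM (SD, n = 3) to 86.3 ± 3.56 CPM (SD, n = 3), at −0.90 with a standard error of 0.0996 (edgeR adjusted p = 0.000358), and passed in each setting that left libraries out. PRDX1 (−0.39, 0.000941) and ME1 (−0.76, 0.00258) fell and kept their call with any 1 library left out, but not with Empty 2 and 3 both left out, when PRDX1 was at −0.31 (0.0699) and ME1 at −0.38 (0.0983). NQO1 was at 75.1, 158 and 172 CPM in Empty 1, 2 and 3 and at 38.8, 42.8 and 30.5 CPM in the sgZHX3-3 libraries. The means of the 12 called genes lay at 0.11, 0.63 and 0.79 log2 units from the mean of all libraries in Empty 1, 2 and 3, and at −0.48, −0.45 and −0.59 in the sgZHX3-3 libraries, so Empty 2 and 3 stood apart from Empty 1. As a set these genes had a median of −0.26 and a mean of −0.58 (camera adjusted p = 5.82e-11, and 0.219 with an estimated correlation). With Empty 2 and 3 both left out the median was −0.22.

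Several endoplasmic reticulum chaperones fell as well. Of 24 tested genes of the endoplasmic reticulum stress list, 10 were lower and the sensor ERN1 higher, and 13 and 1 adjusted over the list alone. HSPA5, the main chaperone of that compartment, went from 1310 ± 63.4 CPM (SD, n = 3) to 1051 ± 13.5 CPM (SD, n = 3), at −0.32 with a standard error of 0.0524 (edgeR adjusted p = 0.00219). The cochaperones DNAJB9 (−0.43, 0.000497) and DNAJC3 (−0.39, 0.000636) and the secreted factor MANF (−0.41, 0.00121) also fell. All 4 kept their call with any 1 library left out, and of them DNAJB9 alone (−0.35, 0.0455) kept it with Empty 2 and 3 both left out, when HSPA5 was at −0.24, DNAJC3 at −0.33 and MANF at −0.30. The means over the list lay at 0.06, 0.07 and 0.11 log2 units in Empty 1, 2 and 3 and at −0.08, −0.07 and −0.09 in the sgZHX3-3 libraries. Tested together the genes of the list had a median of −0.15 (camera adjusted p = 4.30e-07, and 0.219 with an estimated correlation). With Empty 2 and 3 both left out the median was −0.16.

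Heat shock and immediate early genes also lay higher in Empty 2 and 3 than in Empty 1. The chaperone gene HSPA1A was at 90.8, 186 and 240 CPM in Empty 1, 2 and 3 and at 68.0, 77.2 and 73.7 CPM in the sgZHX3-3 libraries, and DNAJB1 at 195, 343 and 393 CPM against 164, 175 and 165 CPM. Both were chosen after their values were seen, and neither passed (−1.24, edgeR adjusted p = 0.122, and −0.89, 0.124); without Empty 1 both passed (5.13e-06 and 4.89e-07), as they did with DESeq2 (0.00914 and 0.0150) and limma-voom (0.0162 and 0.0165). HSPA1A shares reads with its near-identical copy HSPA1B and is uncertain. Of 22 tested immediate early genes, which respond to growth signals and handling within minutes, 5 were lower (EGR1, FOSB, IER2, FOS and DUSP1) and DUSP6 was higher, and 11 were lower and 3 higher adjusted over the list alone. That list had a median of −0.29 (camera adjusted p = 0.00436; adjusted p = 0.478 with an estimated correlation), lost its call without sgZHX3-3 library 1 (0.0513), and was not called with Empty 2 and 3 both left out (0.206), when its median was −0.05. Its means lay at −0.05, 0.13 and 0.33 log2 units in Empty 1, 2 and 3 and at −0.25, −0.13 and −0.03 in the sgZHX3-3 libraries. Of 22 tested p53 targets, 3 were lower and 0 higher, with the same counts adjusted over the list alone; these were MDM2, AEN and RRM2B. The p53 list had a median of −0.12 (camera adjusted p = 0.0254; adjusted p = 0.422 with an estimated correlation) and lost its call without Empty 2 (0.0503), Empty 3 (0.0724) or sgZHX3-3 library 3 (0.0641), with a filter of 1 CPM in 3 libraries (0.0511), and with Empty 2 and 3 both left out (0.546), when its median was 0.0045.

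**Figure D2:**
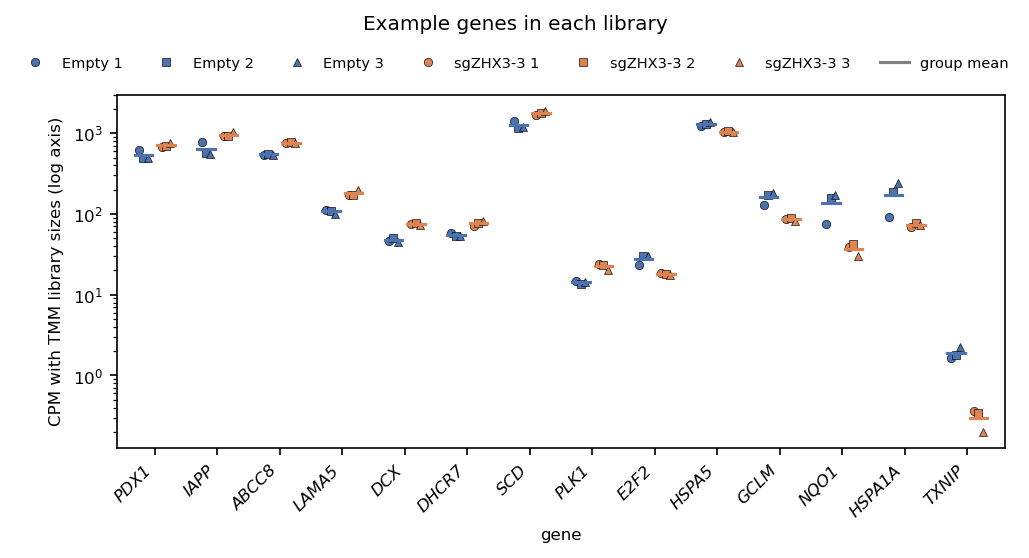
CPM with TMM library sizes on a log axis for 14 genes; each symbol is 1 library (blue, Empty; orange, sgZHX3-3) and bars are group means. HSPA1A lay at 90.8 CPM in Empty 1 against 186 and 240 CPM in Empty 2 and 3, while the ABCC8 group means of 546 and 765 CPM had little spread.

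Most genes that make and take up cholesterol rose. Of 24 tested genes, 17 were higher and 0 lower, 19 were higher and 0 lower adjusted over the list alone, and all 24 had a fold change above 0. DHCR7, the reductase of the last step to cholesterol, went from 54.9 ± 2.60 CPM (SD, n = 3) to 76.8 ± 4.93 CPM (SD, n = 3), at 0.49 with a standard error of 0.0631 (edgeR adjusted p = 0.000516), and the squalene epoxidase SQLE rose by 0.41 (0.000749). Both kept their call with any 1 library left out, and neither with Empty 2 and 3 both left out, when DHCR7 was at 0.41 (0.0642) and SQLE at 0.32 (0.0589). As a whole the list had a median of 0.31 (camera adjusted p = 1.83e-15, and 0.227 with an estimated correlation) and of 0.22 with Empty 2 and 3 both left out. Its means lay at −0.05, −0.20 and −0.21 log2 units in Empty 1, 2 and 3 and at 0.11, 0.15 and 0.20 in the sgZHX3-3 libraries. Empty 1 thus lay nearer the sgZHX3-3 libraries than Empty 2 and 3 did.

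Some fatty acid synthesis genes rose as well. Of 17 tested genes 6 were higher and 0 lower, with the same counts adjusted over the list alone: SCD, FADS1, FADS2, ACACA, ACLY and FASN. SCD, which puts the double bond into stearate, went from 1256 ± 136 CPM (SD, n = 3) to 1797 ± 102 CPM (SD, n = 3), at 0.52 with a standard error of 0.0734 (edgeR adjusted p = 0.000883). The fatty acid synthase FASN rose by 0.54 (0.00180) and the carboxylase ACACA by 0.33 (0.00146). All 3 kept their call with any 1 library left out, and ACACA (0.37, 0.0431) with Empty 2 and 3 both left out, when SCD was at 0.35 and FASN at 0.40 without passing. The list had over all tested members a median of 0.14 (camera adjusted p = 0.000131, and 0.227 with an estimated correlation). With Empty 2 and 3 both left out its median was 0.13. The fatty acid oxidation list had 2 lower and 0 higher of 17 tested genes and was not called (0.340).

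Several basement membrane and matrix genes rose in the libraries labelled sgZHX3-3. Of 27 tested genes of matrix and adhesion, 11 were higher and 0 lower, and 14 were higher and 3 lower adjusted over the list alone. LAMA5, a laminin chain of basement membranes, went from 108 ± 6.81 CPM (SD, n = 3) to 180 ± 14.7 CPM (SD, n = 3), at 0.74 with a standard error of 0.0681 (edgeR adjusted p = 5.32e-05). The protease inhibitor TIMP3 rose by 0.81 (6.13e-05), the laminin chain LAMC1 by 0.45 (0.000203), and the collagens COL18A1 and COL4A2 by 0.75 (9.38e-05) and 0.91 (0.000209). These 5 genes passed with any 1 library left out and with Empty 2 and 3 both left out. The means over the list lay at −0.16, −0.15 and −0.20 log2 units in Empty 1, 2 and 3 and at 0.12, 0.21 and 0.18 in the sgZHX3-3 libraries. As a set these genes had a median of 0.24 (camera adjusted p = 1.25e-10, and 0.202 with an estimated correlation), and of 0.24 with Empty 2 and 3 both left out.

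Some neuronal genes and a few signalling genes rose, while most members of their lists did not pass. Of 27 tested neuronal genes 9 were higher and 0 lower, and 12 and 1 adjusted over the list alone. DCX, a microtubule-binding protein of young neurons, went from 47.6 ± 2.86 CPM (SD, n = 3) to 75.6 ± 2.85 CPM (SD, n = 3), at 0.67 with a standard error of 0.0612 (edgeR adjusted p = 5.32e-05), and passed in each setting that left libraries out. The neuronal list had a median of 0.13 (camera adjusted p = 6.49e-05, and 0.219 with an estimated correlation). With Empty 2 and 3 both left out its median was 0.15. Of 23 tested Notch and Wnt genes, the Wnt receptor FZD7 (0.66, 0.000200) and the Notch ligand DLL1 were higher and 0 were lower, with the same 2 adjusted over the list alone. That list had a median of 0.15 (camera adjusted p = 0.0244; adjusted p = 0.229 with an estimated correlation) and lost its call without sgZHX3-3 library 3 (0.0783) and with Empty 2 and 3 both left out (0.218). Of 19 tested genes of epithelial-mesenchymal transition and TGF-beta, 5 were higher, among them the BMP-induced ID3 (0.74, 0.000454), and SNAI1 and TGFBR2 were lower; the list was not called (0.205), with a median of 0.06, a mean of −0.02 and a test direction upward.

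Cell cycle genes went both ways. Of 32 tested genes 6 were higher and 12 lower, and 8 and 14 adjusted over the list alone. The replication clamp PCNA went from 311 ± 14.2 CPM (SD, n = 3) to 235 ± 16.1 CPM (SD, n = 3), at −0.40 with a standard error of 0.0602 (edgeR adjusted p = 0.00123), and E2F2 (−0.63, 0.00133), CCNE2 (−0.74, 0.00192) and MYBL2 (−0.61, 0.00267) also fell. The mitotic kinase PLK1 went from 14.2 ± 0.447 CPM (SD, n = 3) to 22.6 ± 1.96 CPM (SD, n = 3), at 0.67 (0.000311). All 5 kept their call with any 1 library left out; with Empty 2 and 3 both left out PLK1 kept it (0.63, 0.0387), and PCNA (−0.33), E2F2 (−0.37), CCNE2 (−0.49) and MYBL2 (−0.32) did not, with adjusted p from 0.0785 to 0.115. The list as a set had a median of −0.08 and was not called (camera adjusted p = 0.128); it was called without Empty 1 (0.00530) and without sgZHX3-3 library 1 (0.0367). Of 14 tested cyclin D, inhibitor and growth control genes, 2 were higher and 0 lower, CDKN1C and MYCN; CDKN1C, an inhibitor of cyclin-dependent kinases, went from 124 ± 16.4 CPM (SD, n = 3) to 209 ± 13.7 CPM (SD, n = 3), at 0.75 (0.000225), and passed in each setting that left libraries out. That list was not called (0.812), with a median of −0.02 and a test direction upward.

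A few ribosomal protein genes rose and a few cilium genes fell, while most members of both lists did not pass. Of 30 tested cytosolic ribosomal protein genes, all lay above 0, 6 were higher and 0 lower, and 15 and 0 adjusted over the list alone. The list had a median of 0.14 (camera adjusted p = 2.30e-05, and 0.478 with an estimated correlation). With Empty 2 and 3 both left out the median of these genes was 0.12. These genes share reads with many processed pseudogenes and are uncertain. Of 26 tested primary cilium genes, 3 were lower and 0 higher, and 6 and 0 adjusted over the list alone; BBS4 and IFT74 were among the lower. The cilium list had a median of −0.12 (camera adjusted p = 0.00550, and 0.411 with an estimated correlation). With Empty 2 and 3 both left out its median was −0.09.

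Lists of markers of other cell types and of lost identity were not called. In the list of genes normally low in beta cells, 4 were higher and 1 lower of 19 tested and 10 lay above 0, the lower being the lactate dehydrogenase gene LDHA (−0.41, edgeR adjusted p = 0.000358). Among 15 tested markers of dedifferentiation 2 were higher and 3 lower, TXNIP among the lower; 12 of the 15 lay above 0, the median was 0.18 and the mean −0.11. Among 18 tested markers of other islet endocrine cells 4 were higher, among them CRYBA2, LOXL4 and RBP4, and 3 were lower (IRX1, IRX2 and SPINK1); 10 lay above 0, with a median of 0.01, a mean of −0.01 and a test direction upward. Of these the alpha cell transcription factor IRX1 was at −2.56 (0.000707), from 0.852 to 0.137 CPM. The glucagon gene GCG (0.99, 0.0964) lay at 0.190 and 0.377 CPM and did not pass, nor did the somatostatin gene SST (−0.01, 0.976). Of 7 tested exocrine and ductal markers 6 lay above 0, with a median of 0.24; CPA1 was higher and TFF1 lower. CPA1 was at 0.31 (0.0145) and lost its call without Empty 2 (0.0833), Empty 3 (0.0855) or sgZHX3-3 library 2 (0.0637). Of 6 tested mesenchymal, endothelial and immune markers 4 lay above 0 and 0 passed. None of these 5 lists was called, with camera adjusted p of 0.544, 0.812, 0.544, 0.742 and 0.638 in this order.

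The remaining lists were not called either. The inflammatory list of NF-kB and cytokine genes had 2 higher and 4 lower of 16 tested, the lower being CXCL1, IRF1, NFKB2 and NFKBIZ (camera adjusted p = 0.215; 0.0010 without Empty 1 and 0.0383 with a filter of 1 CPM in 3 libraries). The cytokine signalling inhibitor SOCS3 was higher there, at 2.47 (edgeR adjusted p = 0.00110), on counts of 9, 13 and 3 against 35, 53 and 51, and did not pass with Empty 2 and 3 both left out (2.21, adjusted p = 0.0556). Apoptosis regulators had 1 higher and 4 lower of 25 tested (0.104; 0.0367 without sgZHX3-3 library 1 and 0.0395 without sgZHX3-3 library 2). Interferon response genes had 0 higher and 2 lower of 21 (0.239), and of 16 antigen presentation genes 0 passed (0.544). Targets of ATF4 had 4 higher and 1 lower of 26 (0.445), glycolysis and hypoxia genes 2 and 3 of 27 (0.151; 0.0419 with Empty 2 and 3 both left out), and autophagy and lysosome genes 4 (LAMP1, NPC2, HEXA and NPC1) and 2 (SQSTM1 and GABARAPL1) of 25 (0.499). Nuclear genes of oxidative phosphorylation had 1 higher and 0 lower of 30 (0.846). Of 5 metallothioneins 0 passed (0.726). Histone genes had 1 higher of 11 (0.794), with a median of −0.01 and a mean of 0.0084, and chromatin silencing regulators had 1 lower of 19, the replication-linked UHRF1 (0.474). Mitochondrially encoded genes are not in the deposited table and were not analysed here.

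Across the 38 lists with enough tested genes, 12 were called higher and 5 lower by camera with its preset correlation of 0.01. With a correlation estimated for each list 0 were called, and 8 had an unadjusted p below 0.05; the rotation test fry, which does not compare a list with other genes, called 17. Of the lists called by camera, fry did not call granule cargo (0.0534), p53 targets (0.0756) and immediate early genes (0.187), and it called 3 that camera did not: fatty acid oxidation (0.0469), epithelial-mesenchymal transition and TGF-beta (0.0152), and the ZHX family and NF-Y subunits (0.0303). With Empty 2 and 3 both left out camera called 12.

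**Figure D3:**
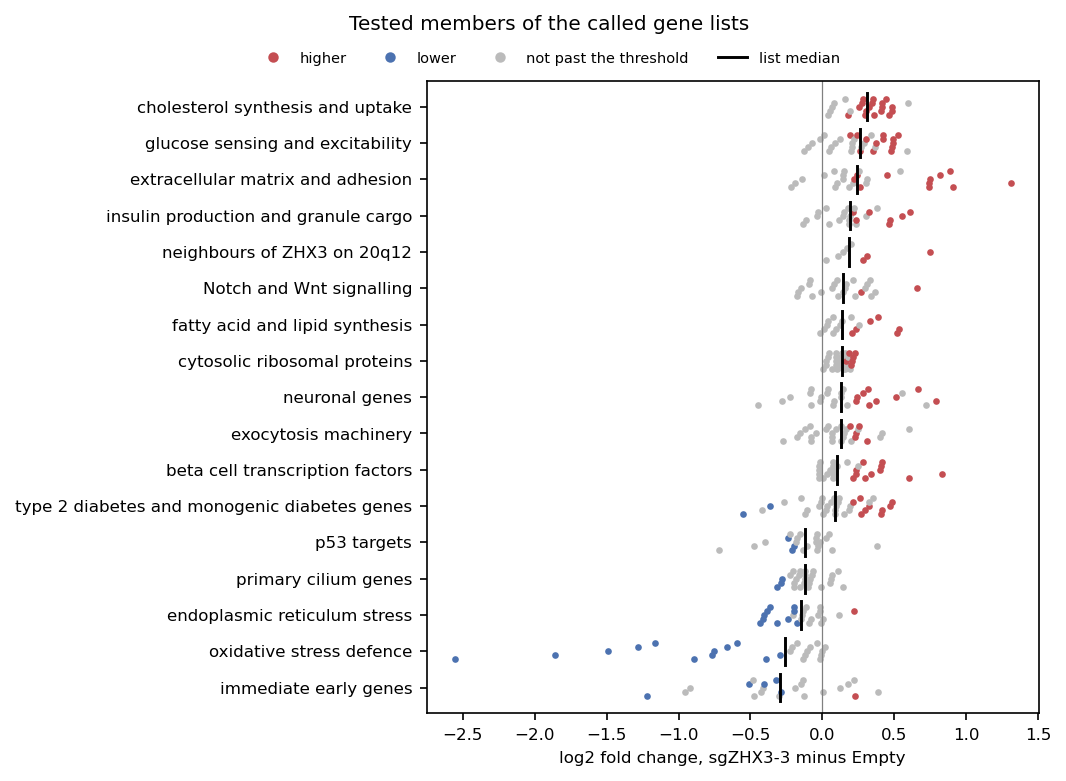
Log2 fold change (sgZHX3-3 minus Empty) of each tested member of the 17 called lists; each point is 1 gene (red, higher; blue, lower; grey, not past the threshold) and black bars are list medians. Medians ran from 0.31 for cholesterol genes to −0.29 for immediate early genes, and 0 of the 17 lists were called once the correlation was estimated by camera, 8 having an unadjusted p below 0.05.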

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

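The alternatives that left out Empty 2 and 3 together or removed a trend with gene span or with transcript length and GC content were chosen after the results were seen. ZHX3 was higher and past the threshold under each of the 16 alternatives, with log2 fold changes from 0.66 (transcript length and GC offset) to 0.78 (without sgZHX3-3 library 1). All 1958 called genes kept their sign with RLE factors, library totals, no filter, DESeq2, limma-voom, the block and each library left out, as did all 1895 of them that passed a filter of 1 CPM in 3 libraries; with the gene span offset 1943 did, and with the transcript length and GC offset 1957. With the gene span offset 890 genes were higher and 949 lower (845 and 741 of them shared with the calls reported), and with the transcript length and GC offset 1136 and 1099 (907 and 641 shared). With library totals only, 1272 genes were lower. The TMM factors dropped there were 1.004 to 1.018 in Empty and 0.984 to 0.991 in the sgZHX3-3 libraries. Without them the median log2 fold change of all tested genes was −0.038, against −0.002 with them, so the values shifted downward as a whole. With a log2 fold change of at least 1, 60 were higher and 46 lower, and with an adjusted p below 0.01, 467 and 194, as stricter limits must give fewer. Leaving out 1 library gave 474 to 1792 higher and 184 to 1499 lower genes and 14 to 19 called lists. Without both Empty 2 and 3, 209 were higher and 40 lower; fewer samples are part of the cause, and any other part was not tested. With an estimated correlation camera called 0 lists, 8 having an unadjusted p below 0.05. A correlation above the preset 0.01 widens the spread that camera allows for a list. The estimate was 0.51 for cholesterol, 0.45 for ribosomal protein and 0.25 for oxidative stress defence genes. It was −0.0089 for the diabetes list, which lost its call too, so correlation alone does not account for each lost call. The unadjusted camera p of that list rose from 0.00454 to 0.0307, though its correlation lay below the preset one. The setting thus differs in more than the correlation. The 0 called lists and the adjusted p values beside each list therefore do not by themselves measure correlation between genes. Any other part was not tested. The rotation test fry called 17, of which 14 were among those of camera. With no filter HSPA6, HMOX1, NQO1, OSGIN1, SRXN1, TXNRD1, IAPP, MAFA and SLC30A8 were no longer called; with the transcript length and GC offset the same held for HSPA6, NQO1, OSGIN1, CACNA1C and MYBL2, and OSGIN1 and MAFA also lost their call with RLE factors.

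With the replicate number as a block, 516 genes were higher and 239 lower, 516 and 237 of them called without it. Same-numbered libraries correlated at −0.138, 0.0685 and −0.142 after group means were removed, so the numbers carried no sign of a pairing, and the block spends degrees of freedom. With the block KCNJ11 (0.102), CPA1 (0.0620), NFYC (0.0755) and SLC30A8 (0.0626) lost their edgeR call, and DNAJB1 (0.0482) and the NF-kB list (0.0288) were called.

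Of the called genes named, PTPRT turned, to −0.027 with the gene span offset, because that offset removes the trend with span by construction; for the other turns the cause was not tested. No called list turned its test direction, but the median of the p53 targets was 0.0045 with Empty 2 and 3 both left out. In that setting the median alone also turned for the genes normally low in beta cells (−0.032) and the ZHX family and NF-Y subunits (0.030), and the test direction turned for the lists of dedifferentiation (median 0.093), other islet endocrine markers (−0.043), exocrine and ductal markers (−0.036), cyclins D (−0.046), autophagy and lysosome (0.033) and chromatin silencing (−0.024), and the value for INS (−0.014), NKX2-2 (−0.066), NEUROD1 (−0.032), PAX6 (−0.032) and SLC2A2 (−0.072). With 1 library left out, list medians ranged from 0.10 to 0.22 for dedifferentiation, 0.053 to 0.35 for exocrine and ductal markers, −0.064 to 0.024 for cyclins D, −0.029 to 0.026 for oxidative phosphorylation, −0.11 to 0.083 for metallothioneins and −0.077 to 0.043 for histone genes. In the same settings the median alone changed sign for the genes normally low in beta cells (−0.023 to 0.081), other islet endocrine markers (−0.0059 to 0.10), chromatin silencing (−0.031 to 0.012) and the ZHX family and NF-Y subunits (−0.077 to 0.020). Gene values ranged from −0.015 to 0.025 for NEUROD1, −0.0064 to 0.11 for SLC2A2, −0.17 to 0.23 for SST and −0.0078 to 0.058 for TOP1. With library totals only the median of other islet endocrine markers was −0.030, NEUROD1 was at −0.033, PAX6 at −0.0059 and TOP1 at −0.0099; with the gene span offset NEUROD1 was at −0.0088; with the transcript length and GC offset ZHX1 was at 0.015. SST was at 0.0015 with the block and at 0.034 with limma-voom.

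Depth limits the precision of rare genes such as GCG, which rested on 8, 8 and 13 counts in Empty and 18, 19 and 21 in the libraries labelled sgZHX3-3.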

Other observations

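The tests of a copy gain, of reads from PLCG1, of exchanged labels and of the oxidative genes against Empty 1 alone, and the added S-phase, G2/M and heat shock lists, were chosen after the results they concern were seen.

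Most genes of an S-phase list made elsewhere were lower. Of 34 S-phase genes from Seurat that are not in the fixed cell cycle list, 29 were lower and 0 higher in the libraries labelled sgZHX3-3, with a median log2 fold change of −0.30 (camera adjusted p = 5.59e-22; adjusted p = 0.257 with an estimated correlation). Of 42 G2/M genes 3 were higher (PSRC1, CENPE and HMMR) and ANP32E was lower, with a median of −0.02 and a test direction upward (0.742; 0.928 with an estimated correlation). The median of the G2/M list lay 0.2775 above that of the S-phase list. The mean of the G2/M genes less that of the S-phase genes was 0.03, −0.11 and −0.12 in Empty 1, 2 and 3 and 0.32, 0.32 and 0.30 in the sgZHX3-3 libraries; a two-sided exact permutation test gave p = 0.1, the smallest that 3 against 3 libraries can give. Since the mitotic genes PLK1, CCNB1 and AURKA of the fixed list rose while the G2/M list did not pass, a change of cell cycle phase stays open.

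Genes with a long genomic span were more often higher than shorter ones. Of 673 tested genes that span over 300 kb, 215 were higher (31.9%, 95% exact interval 28.4% to 35.6%, over genes, which are not independent replicates) and 4 lower (DIAPH3, GAREM, MIR4435-2HG and SATB1-AS1), with a median log2 fold change of 0.19. Of the 4839 genes of 30 to 100 kb, 5.62% were higher and 6.01% lower. The median of the over 300 kb genes less that of the 10 to 100 kb genes, as a deviation from the mean of all libraries, was −0.09, −0.09 and −0.15 in Empty 1, 2 and 3 and 0.12, 0.12 and 0.09 in the sgZHX3-3 libraries. PTPRT, PTPRN2 and CACNA1C are among the long genes, as are SORCS2, GRIN2A, ADAM12, SDK2 and SPON1 of the strongest rises.

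For the long genes a trend with transcript length, GC content or expression is argued against, since after matching on these the difference was 0.2318 (95% bootstrap interval 0.2035 to 0.2584, 2000 draws; 0.223 unmatched). A state of Empty 2 and 3 stays open: against Empty 1 alone the difference was 0.2142, but that is a single library. The design offers the guide as a biological cause, but does not separate it from other differences between the groups. A change in transcription, in RNA turnover or in the share of unspliced RNA may be behind the pattern. None of these was tested.

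ZHX3 RNA was higher in the libraries labelled sgZHX3-3. A gain of the chromosome region is argued against, since the median of 5 neighbours was 0.14 against 0.75 for ZHX3. Reads of the overlapping PLCG1 stay open as a cause, though PLCG1 gained 31.15 CPM (standard error 9.95) and ZHX3 71.3 CPM (standard error 5.53). The strand setting is not given, so reads of PLCG1 could be counted for ZHX3 alone. The gain of PLCG1 does not bound such reads. The trend with gene span is argued against, since ZHX3 was at 0.7045 once that trend was removed. An exchange of the labels between the groups stays open: the lowest ZHX3 value in the libraries labelled sgZHX3-3 was 1.524 times the highest in those labelled Empty, and the table holds no vector or guide sequence to tell. A biological explanation, such as more RNA made from a gene whose protein is lost, may apply and was not tested.

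Of the oxidative stress defence genes 12 were lower in the libraries labelled sgZHX3-3, and Empty 2 and 3 held more of their RNA than Empty 1. In the same libraries the means of 18 heat shock genes lay at −0.08, 0.37 and 0.49 log2 units in Empty 1, 2 and 3. They lay at −0.26, −0.15 and −0.37 in the sgZHX3-3 libraries. Of these genes DNAJB4, HSPA6, CHORDC1 and DEDD2 were lower and 0 were higher. The heat shock list had a median of −0.27 (camera adjusted p = 9.16e-07, and 0.329 with an estimated correlation). Against Empty 1 alone the median of the heat shock list was −0.08. Against Empty 1 alone the 12 called oxidative genes had a median of −0.5988, against −0.8135 for all Empty libraries, but they were chosen as lower in a comparison that includes Empty 1, so this decides nothing. Over the whole list the median was −0.26 with all libraries and −0.22 with Empty 2 and 3 both left out. A stress state of Empty 2 and 3 cannot be told apart from an effect of the guide, because 1 Empty library remains.

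The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 1958 genes with edgeR and the highest of the others 0, and 1 split, the real one, gave as many.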
